A study of Mus musculus with 2 samples.

How the data were processed

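Histone H3 trimethylated at lysine 9 (H3K9me3), a mark of silent chromatin, was mapped by chromatin immunoprecipitation and sequencing in forebrain of B6NCrl mouse embryos at embryonic day 12.5. The samples form 1 group of 2 biological replicates, with 120 embryos of both sexes pooled in replicate 1 and 68 in replicate 2, and there is no treatment or second tissue to compare. Per the labels, the reads were placed on build mm10. The aligner, the peak caller, its threshold and the read depth of each library are not given in the sources used here, so the precision of a value per peak is unknown and was judged from the spread between the replicates.

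The authors made 4 peak lists in narrowPeak format: 1 list per replicate from its own filtered alignments, 1 list called on the pooled alignments of both replicates, and 1 replicated list derived from these 3. Each replicate list and the pooled list also drew on further files that differed between the replicates and were not used here. The deposited value per peak was read as a linear fold enrichment over control, a ratio, because the format and its range fit that, although no source states the unit in words. The deposited lists also give for each peak the -log10 of its p-value, the -log10 of its q-value and the position of its summit. The rule by which the authors called a peak replicated is not given in the sources used here. Every peak of the replicated list was also in the pooled list with the same values, so its fold enrichment is that of the pooled call.

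The replicate 1 list held 49400 peaks, the replicate 2 list 53686, the pooled list 82858 and the replicated list 26554. The totals of the lists, the overlap and correlation of the replicate lists and the replicated share counted every peak, including 345, 347, 321 and 233 peaks (replicate 1, replicate 2, pooled and replicated list) on sequences not placed on a chromosome. The rotations and all other results of the report used chromosomes 1 to 19, X and Y. Genes and their parts came from GENCODE M21 (21938 protein-coding and 13374 lncRNA genes), and repeats from the soft-masked bases of the reference sequence. Overlaps were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Numba 0.67.0, and figures were drawn with matplotlib 3.10.9. A peak counted as shared with another list, or as held by a gene body, from 1 base of overlap. Each base of a peak was given to the first of promoter (within 1 kb of any annotated transcription start, of the same or another gene), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic sequence that applied. For the gene lists, the alternative within 2 kb of a transcription start used 1 start per gene, the outer end of the gene model, so starts of shorter transcripts inside the gene did not count there. Domains joined peaks 10 kb or less apart. Gene clusters joined members of a list 500 kb or less apart and needed at least 5 members.

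Placement was tested by rotation: all peaks of a chromosome were moved together by 1 random offset along its sequenced bases, wrapping at the end, 10000 times with a fixed seed. This keeps the spacing of the peaks and the layout of the genes. The p-values are two-sided permutation p-values from these rotations, the smallest of which is 0.0002, and they were adjusted by the Benjamini-Hochberg method over the 7 gene features, over the 5 counts of primer binding sites, over the repeat and GC measures, or over the 15 gene lists, with 0.05 as the threshold. The overlap of the replicate lists was set against 100 rotations of the replicate 2 list. Because the samples form 1 group, these tests ask where the peaks lie in the genome and not whether conditions differ. Shares of peaks carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

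The gene lists, the sequences of the retroviral primer binding sites, the tests and the settings to vary were fixed before the data were examined, except where a test is said to have been chosen later. Genes were named by 1 rule: the 10 protein-coding genes with the most replicated peak bases, the 10 whose bodies held the replicated peaks of highest fold enrichment, and the 2 members of each list with the most replicated peak bases, each with a peak in both replicate lists as well. Where a list had 5 or fewer members with a peak, and for other examples outside the rule, members were chosen after their values were seen. A control that searched for the primer binding sequences reversed was void, because none of the 5 reversed sequences occurs in the genome.

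The rotation test of gene lists was tested on simulated data with the 21938 protein-coding genes. With peaks placed by rotation, 2.67% of the tests in 100 simulations of the 15 lists had p under 0.05 (1000 rotations each). These peaks were placed in the way that the test assumes. The rate therefore checks the procedure, and not whether rotation is a fair comparison for real peaks. With peaks planted in 100 of the 394 Zfp-numbered genes the test found the excess in 100% of the simulations, and with peaks planted in 10 of the 40 germline genes in 92%. The motif test used in the closing section gave p under 0.05 in 7% of the simulations without a difference and in 100% of those with 3 times the density. Copies were simulated independently for each peak, so these rates do not carry over to copies clumped in few peaks.

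The alternatives tried were a stricter threshold (q of 0.01 or less), the pooled list, each replicate list alone, other definitions of overlap and promoter, other merge distances and cluster gaps, autosomes only, and random gene sets matched on gene length in 20 bins. Peaks found in both replicate lists, and peaks of sequence in which 90% or more of the 31-base words occur in the genome at 1 place, were added as alternatives after the data were seen. Sequences not placed on a chromosome were left out of the tests, because a rotation needs a chromosome.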

Results

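H3K9me3 was mapped in mouse forebrain at embryonic day 12.5 in 2 biological replicates of 1 group. The replicate 1 list held 49400 peaks over 15.5 Mb and the replicate 2 list 53686 peaks over 15.7 Mb. On the placed chromosomes alone they covered 0.576% and 0.583% of the sequenced bases. The median peak was 246 bases wide in replicate 1 and 233 bases in replicate 2. The pooled list covered 31.3 Mb in 82858 peaks, and the replicated list 16.2 Mb in 26554 peaks with a median width of 489 bases. The fold enrichment of a peak over control is the authors' own value throughout. Its median was 3.07 in replicate 1, 3.06 in replicate 2 and 3.16 in the replicated list. A q-value of 0.05 or less was reached by 64.1% of the replicate 1 peaks, 37.7% of the replicate 2 peaks and 98.6% of the replicated peaks.

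Peaks of low q-value in either replicate lay more often at a peak of the other than weak peaks did. Of the replicate 1 peaks, 39.4% (19479) overlapped a replicate 2 peak, and of the replicate 2 peaks, 37.0% (19874) overlapped a replicate 1 peak. After rotation of the replicate 2 list, 1.47% ± 0.273 (SD, 100 rotations) of the replicate 1 peaks were overlapped, with a highest value of 2.32%. Among peaks with q of 0.0001 or less, 79.3% in replicate 1 and 85.6% in replicate 2 were shared, against 25.8% and 26.3% of the peaks with q above 0.05. These shares counted any peak of the other list. With only the 10000 peaks of lowest p kept in each list, 34.6% and 35.8% were shared, and with q of 0.01 or less in both lists 26.2% and 47.2%. The bases covered in both lists were 0.203 of those covered in either (Jaccard index). When 50% of both peaks had to overlap, the mean share fell from 38.2% to 19.8%. Across the 18116 pooled peaks that overlapped a peak of each replicate, the fold enrichment in the replicates had a Spearman rho of 0.266 and a Pearson r of 0.33 on the log2 scale. Peaks are not independent replicates, so no p is given.

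**Figure D1:**
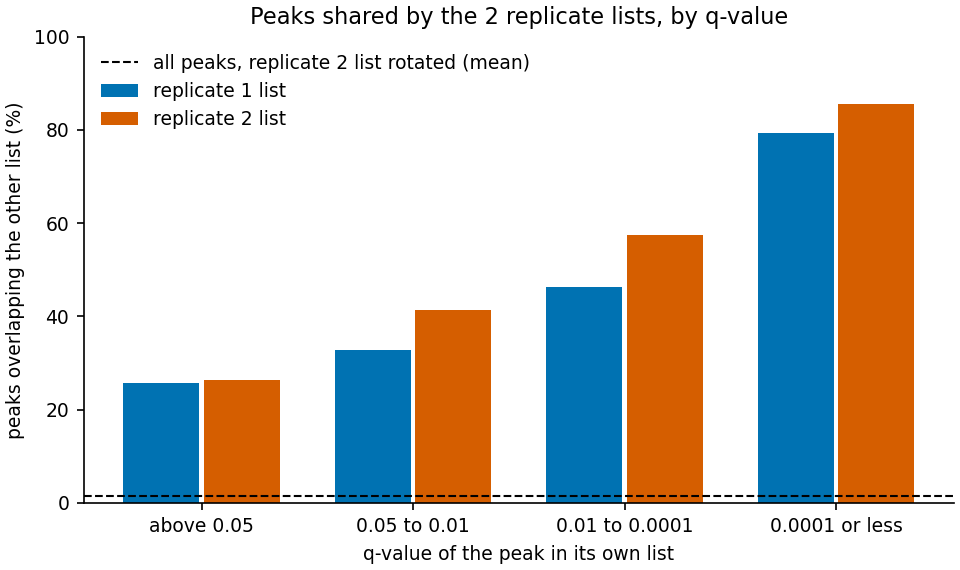
Share of the peaks of each replicate list that overlap a peak of the other list (percent, y axis) by the q-value of the peak in its own list (x axis), with the mean over rotations as a dashed line. The bars rise from 25.8% (replicate 1) and 26.3% (replicate 2) at q above 0.05 to 79.3% and 85.6% at q of 0.0001 or less.

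Of the pooled peaks, 32% (26554 of 82858; exact 95% interval 31.7 to 32.4%) were in the replicated list. The share was 4.88% in the decile of lowest fold enrichment and 95.6% in the highest, where fold enrichment was 3.49 or more. With q of 0.01 or less it was 57%, and when 50% of the pooled peak had to be covered in each replicate list it was 12.2%. The replicated list also held 8710 peaks, with a median fold enrichment of 2.90, that did not overlap a peak of each replicate list, against 3.36 for the 17844 that did.

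Chromosome 7, rich in zinc finger and receptor gene clusters, had the highest peak coverage, with 16.0 ± 0.384 kb per Mb (SD, n = 2) and 30.0 replicated peaks per Mb. Chromosome 17 followed with 10.9 ± 0.211 kb per Mb and chromosome 4 with 8.84 ± 0.239 kb per Mb, against 5.80 ± 0.0478 over all chromosomes. The X chromosome held 1.80 ± 0.307 kb per Mb, the lowest value after the Y chromosome, which held 15 replicated peaks. These differences were larger than the spread between the replicates and were not tested further. With embryos of both sexes pooled, the X and Y chromosomes had fewer copies than the autosomes. Copy number and multi-copy sequence were not weighed by chromosome, so low coverage there cannot be read as little H3K9me3. With q of 0.01 or less, the coverage was 7.73 ± 2.99 kb per Mb (SD, n = 2) on chromosome 7, 0.641 ± 0.162 on the X chromosome and 2.51 ± 0.903 over all chromosomes, a wider spread between the replicates for chromosome 7 and overall.

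**Figure D2:**
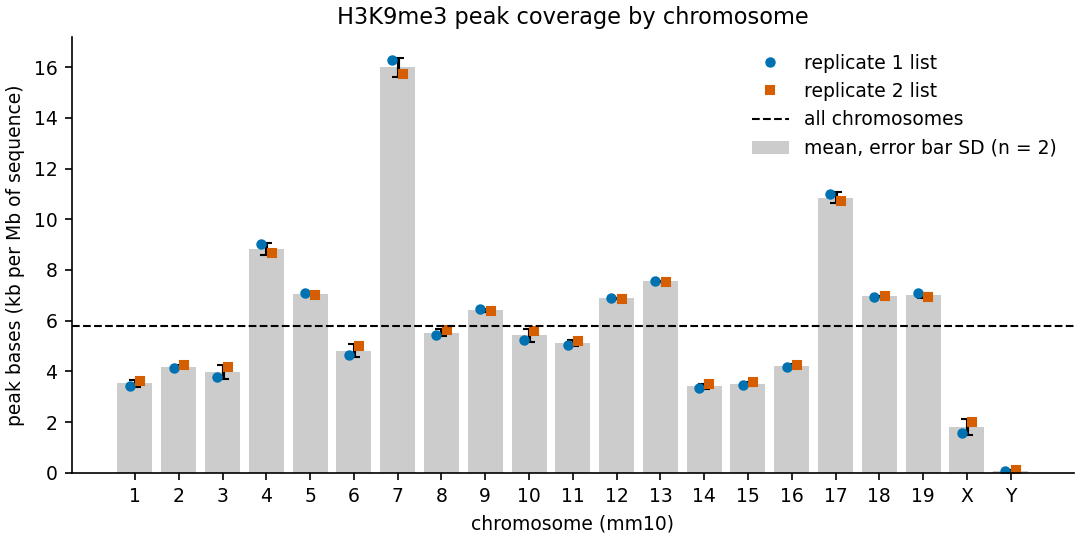
Peak bases per Mb of sequence (kb per Mb, y axis) by chromosome (x axis), as the mean of the replicate lists (bars), SD (error bars, n = 2) and each replicate (points). Chromosome 7 stands highest at 16.0 kb per Mb, and the X chromosome holds 1.80 kb per Mb against 5.80 over all chromosomes (dashed line).

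Coding exons and sequence between genes held more H3K9me3 than rotated peaks placed there, and introns held less. Coding exons took 2.42% of the replicated peak bases against a rotation mean of 1.06% ± 0.0995 (SD), a ratio of 2.28, and intergenic sequence took 60.5% against 51.4% (1.18). Introns took 29.2% against 39.9% (0.733). The adjusted p was 0.000467 for all 3 features, from the smallest p that the rotations can give. The gene families described below were not set apart here, so the test cannot show whether the excess is general to coding exons. The last exons of the Zfp-numbered genes alone held 175204 replicated peak bases. For 3' UTRs the ratio was 1.32 (adjusted permutation p = 0.0108) and for 5' UTRs 1.63 (adjusted p = 0.0498). Promoters took 5.02% against 5.24% (adjusted permutation p = 0.715), and other exons 1.01% against 1.05% (adjusted p = 0.715), neither past the threshold. Counted by summit, promoters held fewer peaks than rotated ones, 4.25% against 5.22% (adjusted permutation p = 0.0119), and the 5' UTR and 3' UTR results were lost, with ratios of 1.17 (adjusted p = 0.683) and 1.17 (adjusted p = 0.133). Counted by bases, the 5' UTR result was lost at the stricter threshold (1.63, adjusted permutation p = 0.0512) and in the replicate 1 list alone (1.48, adjusted p = 0.0750). The 3' UTR result was lost in the pooled list (1.11, adjusted permutation p = 0.171) and in the replicate 1 list alone (1.18, adjusted p = 0.0750).

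Peaks were richer in G and C than rotated peaks, 45.6% against 42.2% ± 0.314 (SD; ratio 1.08, adjusted permutation p = 0.0004). Repeat-masked bases made up 33.6% of peak bases against 33.9% after rotation (permutation p = 0.781). The called peaks thus showed no excess over repeats as a whole. Rotated peaks, however, can land in multi-copy sequence, where few peaks were called. Under 10% of the 31-base words were unique in the genome for 0.106% of the replicated peaks, against 9.375% of random windows. The test therefore cannot show whether the mark is enriched over multi-copy repeats.

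H3K9me3 lay over many zinc finger genes, which encode DNA-binding proteins, many of them repressors of retrotransposons. A replicated peak was held by 160 of the 394 Zfp-numbered genes (40.6%) against a rotation mean of 63.0 ± 12 (SD), 2.54 times as many (adjusted permutation p = 0.00075). In a wider list, called C2H2 genes here, it was 169 of 459 against 72.2, 2.34 times as many (adjusted permutation p = 0.00075). Both lists were taken by gene symbol, the wider one adding Zkscan, Zscan, Zbtb and similar names. They therefore leave out C2H2 genes of other names and can include genes with another type of finger. Zfp936 on chromosome 7 (43114229 to 43192109) held 36 replicated peaks over 24.0 kb, with 19.5 ± 3.07 kb (SD, n = 2) in the replicate lists. Zfp943 on chromosome 17 (21962552 to 22071168) held 21.7 kb, with 14.4 ± 1.46 kb in the replicate lists. By contrast, all protein-coding genes held a peak in 3551 cases (16.2%) against a rotation mean of 3548 (permutation p = 0.965). They held fewer than rotated in the pooled list (7324, ratio 0.951, permutation p = 0.001) and in the replicate 2 list (5953, ratio 0.955, p = 0.0044), and in the replicate 1 list the ratio was 0.974 (p = 0.188).

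Within the Zfp-numbered genes, the peaks lay towards the last exon, which encodes the finger array in most such genes. The last exons held 32.6% of the peak bases in these gene bodies against a rotation mean of 10.5% ± 4.12 (SD), 3.09 times as much (permutation p = 0.0002, the smallest the rotations can give). They make up 8.96% of the gene bodies. Within 2 kb of the outer start of the gene neither list passed the test, with 29 Zfp-numbered genes (1.49 times the rotation mean, adjusted permutation p = 0.653) and 30 C2H2 genes (1.33 times, adjusted p = 0.849). In the replicate lists alone the ratio for Zfp-numbered genes was 1.75 (replicate 2) and 1.93 (replicate 1), and for C2H2 genes 1.64 and 1.82. With the pooled list it was 1.62 and 1.53.

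**Figure D3:**
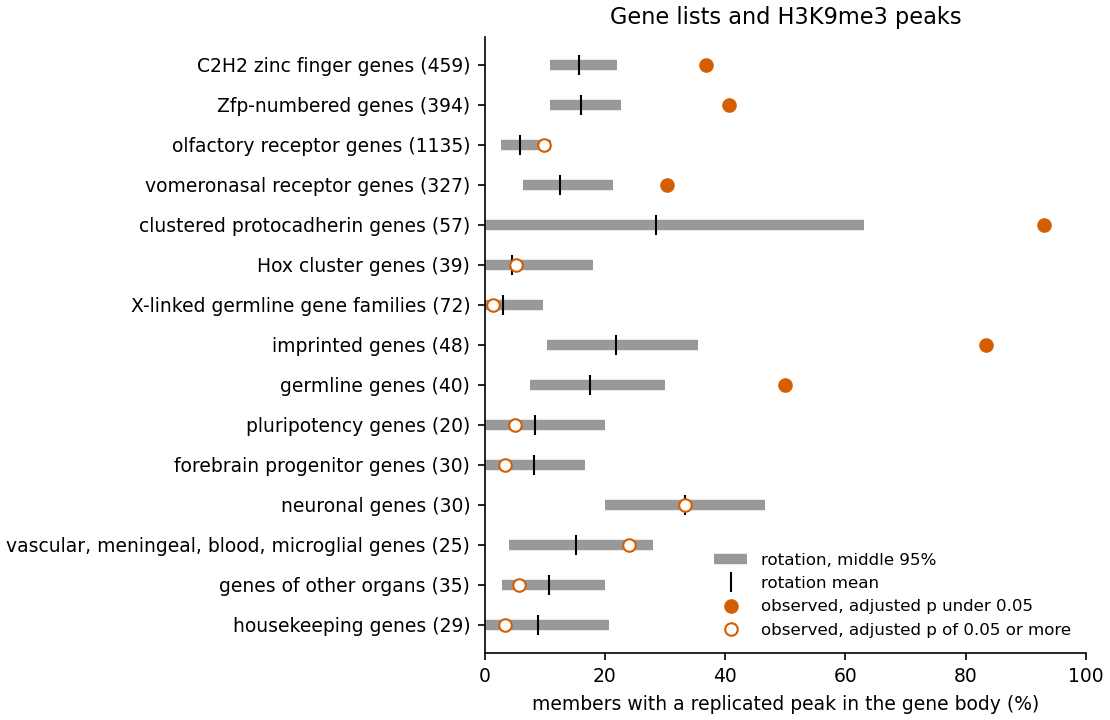
Percent of the members of each gene list with a replicated peak in the gene body (x axis; members in parentheses), as observed (points, filled where the adjusted p was under 0.05) with the mean (tick) and middle 95% (grey bar) of 10000 rotations. Imprinted genes stand at 83.3%, protocadherin genes at 93.0%, germline genes at 50% and Zfp-numbered genes at 40.6%, all above the rotations.

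Vomeronasal receptor genes, which encode pheromone receptors, held peaks in 99 of 327 cases against a rotation mean of 41.2 ± 12.7 (SD), 2.40 times as many (adjusted permutation p = 0.0012). The ratio was 1.85 in the replicate 2 list, 1.82 in the replicate 1 list and 1.5 in the pooled list. Vmn2r60 on chromosome 7 (42107770 to 42196208) held 14.4 kb of replicated peak and Vmn2r17 on chromosome 5 (109419688 to 109458459) held 9.10 kb, with 11 ± 0.344 and 5.71 ± 0.666 kb (SD, n = 2) in the replicate lists. Olfactory receptor genes, which encode odorant receptors, held peaks in 111 of 1135 cases against 66.5, a ratio of 1.67 that did not pass the test (adjusted permutation p = 0.259). Olfr398 on chromosome 11 held 5.31 kb and Olfr1349 on chromosome 7 held 4.19 kb. Against random gene sets matched on length, which ignore that these genes lie in clusters, the olfactory ratio was again 1.67 (adjusted permutation p = 0.000429).

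Members of these families lie in clusters, and peaks were counted by cluster too. A member held a peak in 16 of the 17 clusters of Zfp-numbered genes, in 11 of the 16 vomeronasal clusters and in 15 of the 33 olfactory clusters. In 10 Zfp, 9 vomeronasal and 3 olfactory clusters, at least 50% of the members held a peak. Clusters of different families can overlap and count the same peaks. On chromosome 17 the vomeronasal cluster at 22544504 to 23479699 lies within the Zfp cluster at 21008903 to 23599487. Coverage per Mb counts all sequence of a cluster: a C2H2 cluster on chromosome 7 (10487229 to 11402318) held 78.6 kb per Mb with a peak in 0 of 6 members. The cluster of 28 olfactory genes on chromosome 2 (36373519 to 37332772) had a peak in 25 members and 177 kb of peak per Mb, whereas the 227 olfactory genes at 85330779 to 90403897 on the same chromosome had a peak in 2 members and 1.34 kb per Mb. The 4 clusters of Hox genes, which pattern the body axis, held 0 to 5.61 kb of replicated peak per Mb, but 7.62 to 18 in the replicate 1 list and 3.69 to 10.6 in the replicate 2 list.

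**Figure D4:**
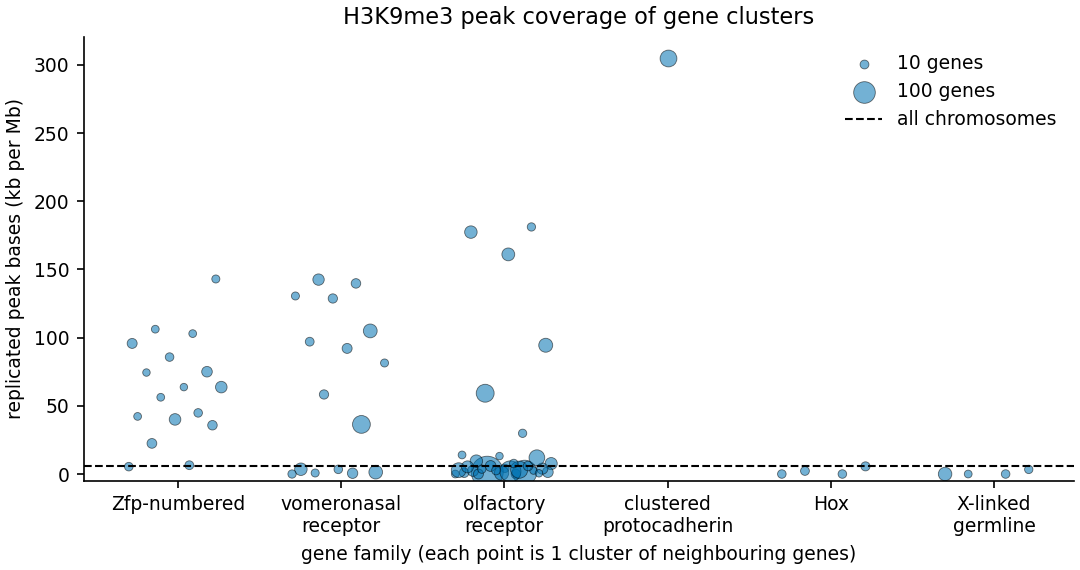
Replicated peak bases per Mb (kb per Mb, y axis) in each cluster of neighbouring genes (points, area by number of genes) by gene family (x axis). The protocadherin cluster stands at 305 kb per Mb, 5 olfactory clusters at 59.2 to 181, and the Hox clusters at or under 5.61 in the replicated list, against 6.0 kb per Mb over all chromosomes (dashed line).

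The clustered protocadherin genes on chromosome 18 encode neuronal adhesion molecules, and the Pcdha and Pcdhg genes among them are read from alternative first exons. The 57 genes formed the most densely marked cluster of those examined, with 278 kb of replicated peak, or 305 kb per Mb. A peak lay in 53 of the 57 genes against a rotation mean of 16.2 ± 11.8 (SD), 3.27 times as many (adjusted permutation p = 0.006). The genes Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, all of the C type at the ends of their arrays, held none in the replicated list, whereas Pcdhac1, also of the C type, held 3 peaks over 1859 bases. Pcdhga1 (37661793 to 37841873) held 87.3 kb, with 76.2 ± 5.45 kb (SD, n = 2) in the replicate lists, and Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5, whose models overlap it, held 63.8 to 84.1 kb. The highest peak in them (37765728 to 37769294) had a fold enrichment of 8.02. The read-through models Gm42416, Gm37013 and Gm37388 span the cluster and held 258 to 268 kb. The 57 gene models overlap, so a peak can count for several genes: the strongest peaks of the 53 genes were 28 distinct peaks. For 25 of the 53 genes the strongest summit lay in a coding exon. It lay within 1 kb of an annotated start of the gene itself for 3. The ratio was 2.0 in the replicate 2 list (54 genes), 2.24 in the replicate 1 list (56 genes, Pcdhgc3, Pcdhgc4 and Pcdhgc5 among them), 1.82 in the pooled list (56 genes) and 28.1 for peaks within 2 kb of the outer start of the gene.

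**Figure D5:**
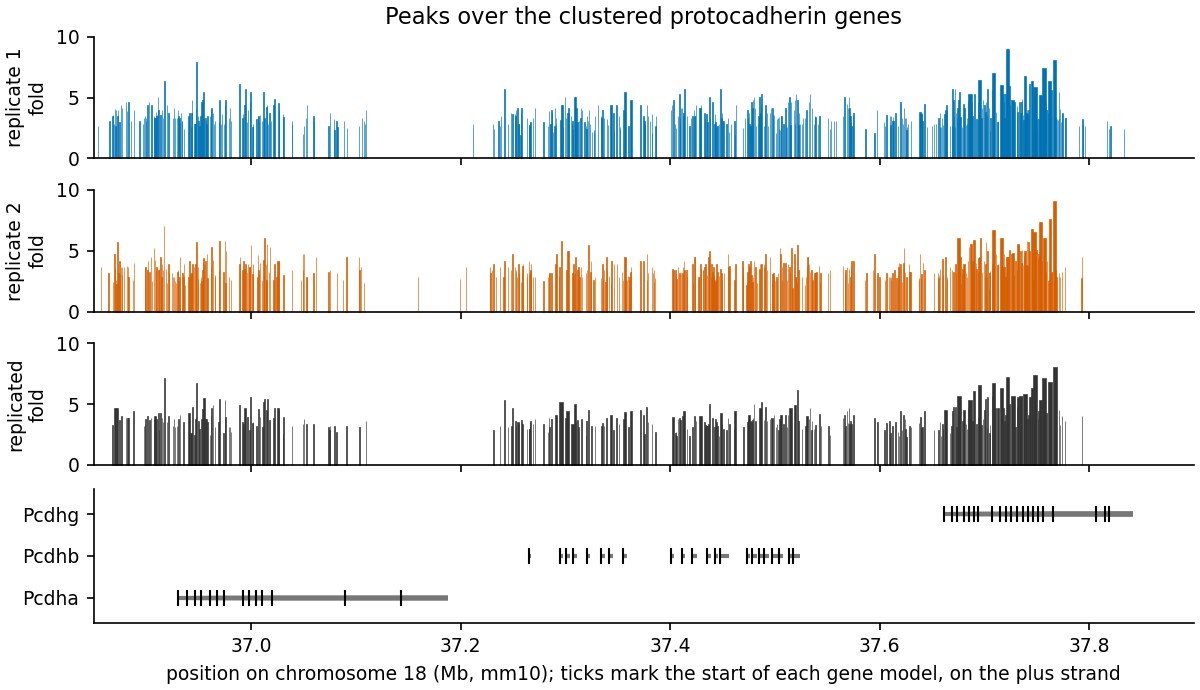
Peaks over the clustered protocadherin genes of chromosome 18 (x axis, position in Mb on mm10), with fold enrichment (y axis) in each replicate list and in the replicated list, above the gene models with a tick at each start. A replicated peak lies within 2 kb of the outer start of 53 of the 57 genes, and the highest, at 8.02 in the replicated list, lies near the 3' end of the Pcdhga and Pcdhgb starts.

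Imprinted genes, which are expressed from the maternal or the paternal copy, held a peak in 40 of 48 cases against a rotation mean of 10.5 ± 3.00 (SD), 3.81 times as many (adjusted permutation p = 0.00075). For 24 of the 40 the summit of the strongest peak lay in a promoter, for 21 within 1 kb of an annotated start of the gene itself, and the strongest peaks had fold enrichments of 2.68 to 7.24. Gnas on chromosome 2 (174284320 to 174346744), a G protein subunit, held 10.1 kb of replicated peak, with 8.51 ± 0.178 kb (SD, n = 2) in the replicate lists. Kcnq1 on chromosome 7 (143106362 to 143427042), a potassium channel whose gene contains the Kcnq1ot1 transcript, held 7.24 kb, with 6.63 ± 1.06 kb. Grb10 (7.24-fold), Mest (6.72-fold), Snrpn (6.33-fold) and Plagl1 (5.82-fold) were among the genes with the strongest promoter peaks. No replicated peak lay in the gene bodies of H19, Igf2, Zim1, Ascl2, Tssc4, Phlda2, Dlk1 or Mirg. However, 43 of the 48 genes held a pooled peak and 41 a replicate 1 peak. With 5 kb added on each side of the gene body, 42 of the 48 held a replicated peak. The imprinted genes share peaks, 29 distinct strongest peaks for 40 genes. The ratio was 2.20 in the replicate 2 list, 2.61 in the replicate 1 list, 2.07 in the pooled list and 8.51 within 2 kb of the outer start of the gene.

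Germline genes, active in germ cells and silent in most other tissues, held a peak in 20 of 40 cases against a rotation mean of 7.01 ± 2.36 (SD), 2.85 times as many (adjusted permutation p = 0.00075). For 15 of the 20 the strongest summit lay within 1 kb of an annotated start of the gene itself. Ddx4, a germ cell RNA helicase, had a 6.33-fold peak (5.56 and 4.45 in replicates 1 and 2), Sycp1 of the synaptonemal complex a 5.82-fold peak, and Dazl, a germ cell RNA-binding protein, a 3.98-fold peak. Taf7l on the X chromosome (134460118 to 134476490) held 1.48 kb of replicated peak and Meioc on chromosome 11 (102663716 to 102682237) held 1.30 kb, with 1.31 ± 0.0311 and 1.18 ± 0.165 kb (SD, n = 2) in the replicate lists. Within 2 kb of the outer start of the gene the ratio was 11.6. It was 2.09 in the replicate 1 list and 1.64 in the pooled list, and the result was lost in the replicate 2 list alone, with 19 of 40 genes and a ratio of 1.40 (adjusted permutation p = 0.132).

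Genes that work in the developing forebrain were not past the test in either direction. For the progenitor genes a lack of peaks could not have passed, since the 2.5th percentile of the rotations was 0 genes. At the stricter threshold 0 of these 30 genes held a peak, with an adjusted permutation p of 0.255. Of 30 forebrain progenitor genes, 1 held a replicated peak against a rotation mean of 2.47 (adjusted permutation p = 0.683): Gli3, a hedgehog effector, with a 2.59-fold peak in its 3' UTR. In the replicate 2 list 7 progenitor genes held a peak, a ratio of 1.62 (adjusted permutation p = 0.295), in the replicate 1 list 3 (0.764), and in the pooled list 6 (1.05). Of 30 neuronal genes, 10 held a peak against 9.98 (adjusted permutation p = 1), with a ratio of 1.30 in the replicate 2 list and 0.845 in the replicate 1 list. For 7 of these 10, among them Syt1 (6.08-fold) and Reln (4.65-fold), the strongest summit lay in an intron. Nrxn1, a presynaptic adhesion gene on chromosome 17, held 3.02 kb, with 2.59 ± 0.939 kb (SD, n = 2) in the replicate lists, and Reln on chromosome 5, a secreted guide of neuron placement, 2.33 kb, with 1.49 ± 0.0361 kb.

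Of 20 pluripotency genes, 1 (Dppa3, by 30 bases at its promoter) held a peak (ratio 0.602, adjusted permutation p = 1), and of 29 housekeeping genes, 1 (Tbp, in an intron) did (ratio 0.387, adjusted p = 0.683). Among 25 markers of vessels, meninges, blood and microglia, cells that the tissue could also contain, 6 held a peak (ratio 1.58, adjusted permutation p = 0.573). Pdgfrb, a pericyte receptor, held 1.13 kb and Cx3cr1, a microglial receptor, 0.772 kb. Of 35 genes of other organs, 2 held a peak (ratio 0.534, adjusted permutation p = 0.683). Cyp3a11, a liver cytochrome, held 9.52 kb, with 6.69 ± 0.214 kb (SD, n = 2) in the replicate lists, and Ckm, muscle creatine kinase, 1 peak of 628 bases. Of 39 Hox genes, Hoxa9 and Hoxb7 held a peak (ratio 1.14, adjusted permutation p = 1), neither of them in both replicate lists. The Hox ratio was higher in the replicate 2 list (11 genes, 2.99, adjusted permutation p = 0.0720), in the replicate 1 list (10 genes, 3.13, adjusted p = 0.0754) and in the pooled list (12 genes, 2.30, adjusted p = 0.126), without passing the threshold. With the pooled list the ratio was 1.24 for pluripotency, 0.895 for vessel, meninges, blood and microglia and 1.15 for other organ genes. The list of X-linked germline families had 1 of 72 (ratio 0.468, adjusted permutation p = 1). That gene, Slx4ip on chromosome 2, matched the list by its name alone and does not lie on the X chromosome. The ratio was 1.19 in the replicate 2 list, 0.871 in the replicate 1 list and 1.09 in the pooled list. Against length-matched gene sets the ratio was 0.163 (adjusted permutation p = 0.0274). For the pluripotency, housekeeping, Hox and X-linked lists the 2.5th percentile of the rotations was 0 genes. A lack of peaks in these lists could therefore not pass the rotation test.

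Primer binding sites, where a transfer RNA starts reverse transcription, mark full-length endogenous retroviruses. Of 174 sites for tRNA-Pro, 17 (9.77%) lay within a replicated peak, 18.9 times the rotation mean of 0.899 (adjusted permutation p = 0.0005). For tRNA-Lys1,2 it was 5 of 67, 11.1 times the rotation mean (adjusted permutation p = 0.001), and for tRNA-Lys3 3 of 62, 7.58 times (adjusted p = 0.0257). Of 1090 sites for tRNA-Phe, 5 lay within a peak against 6.61 after rotation (ratio 0.756, adjusted permutation p = 0.715), but 119 lay within 1 kb of a peak, 5.12 times the rotation mean (adjusted p = 0.0002). The 18-base site for tRNA-Leu had 0 exact matches in the genome. The tRNA-Lys3 result was lost with peaks found in both replicate lists (2 of 62, ratio 6.67, adjusted permutation p = 0.0972), an alternative chosen after the data were seen. The tRNA-Lys3 ratio was 13.1 in the replicate 2 list (5 of 62), 10.8 in the replicate 1 list (4 of 62) and 10.6 in the pooled list (8 of 62), and the tRNA-Pro ratio was 10.3 in the pooled list. Around the sites much of the sequence occurs at several places in the genome, with a median of 5.29% of 31-base words found at 1 place for tRNA-Phe and 1.47% for tRNA-Pro, against 94.2% in replicated peaks.

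The replicated peaks formed 12268 domains with a median width of 553 bases. Most, 9110, were single peaks, whereas 699 joined at least 5 peaks and held 49.4% of the peak bases and 43.2% of the peaks, and 53 were wider than 100 kb. The domain with the most peak bases (chromosome 7, 17855903 to 18187678) spanned 332 kb over the Ceacam11, Ceacam12 and Ceacam13 genes, with 157 replicated peaks over 120 kb and 80.8 and 73.3 kb in replicates 1 and 2. The next held the Pcdhga and Pcdhgb genes (chromosome 18, 37594742 to 37777076) with 106 kb. Others lay over Gm12887 (chromosome 4, 121468649 to 121736302; 106 kb), the Pramef12 and Pramef20 genes (chromosome 4, 144347020 to 144593266; 97.8 kb), Scgb2b26 (chromosome 7, 33776778 to 33968809; 83.7 kb) and the cathepsin genes Ctsm and Cts3 (chromosome 13, 61428934 to 61666122; 75.1 kb). Those of Zfp978, Zfp982 and Zfp985 held 68.0 kb, of Ceacam5 and Ceacam14 67.5 kb, and of the Pcdhb genes 67.3 kb. A domain on chromosome 12 (114248080 to 114487794) held 78.2 kb and no gene annotated as protein-coding. Domains were named by such genes only, so genes of other types in it were not looked for. With the pooled list there were 34115 domains, and with the replicate lists alone 22470 and 25827.

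The highest peaks in protein-coding genes outside the protocadherins lay at Ccdc177, Klf14, Tcfl5, Zfp180, Zfp90 and Asmt. The peak in the body of Ccdc177 on chromosome 12 (80755901 to 80759482) had a fold enrichment of 11.1, with 11.1 ± 0.117 (SD, n = 2) in the replicate lists. Klf14, a Krüppel-like transcription factor on chromosome 6, had 11 in a peak over its start, with 9.92 ± 0.421, and Tcfl5, a basic helix-loop-helix factor on chromosome 2, had 9.57, with 8.66 ± 1.09, in a peak (180642652 to 180644773) that lay mostly upstream and covered 0.275% of the gene. Zfp180 on chromosome 7 had 9.19 in its 3' UTR (6.96 ± 1.44 in the replicate lists), and Zfp90 on chromosome 8 had 8.53 (8.12 ± 0.0131). Asmt, which completes melatonin synthesis, lies on the X chromosome (170672644 to 170678054), and its peaks covered 91.8% of the gene and reached 8.17 in a coding exon (7.44 ± 0.0061).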

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

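The look at unplaced sequences and the tests of single-copy peaks, of bases outside the repeat mask, of multi-copy sequence at the primer binding sites, of sharing by q-value and of the share of the shorter list were chosen only after the results they address were seen. Outside the rotation tests and the coverage of chromosomes, genes and domains, 233 replicated peaks lay on sequences of the assembly that are not placed on a chromosome, a signal outside the main measurement. They were counted only in the totals of the lists, the comparisons between lists and the replicated share. The 233 peaks fell on 25 of the 44 such sequences, 60 of them on 1 sequence. Their 264 kb made up 1.64% of the replicated peak bases, or 50.4 kb per Mb, with 46 and 43.6 kb per Mb in replicates 1 and 2 against 5.80 on the placed chromosomes. Their median fold enrichment was 3.45 against 3.16 on the placed chromosomes.

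Zfp-numbered and vomeronasal receptor genes held more peaks than rotated peaks gave, and reads shared between such close paralogs could place 1 signal at several genes. With only the 16464 replicated peaks of single-copy sequence, the Zfp-numbered genes held peaks at 2.67 times (permutation p = 0.0002, the smallest possible) and the vomeronasal receptor genes at 2.41 times the rotation mean (p = 0.0008), which argues against shared reads as the whole cause. Peaks confined to interspersed repeats within the Zfp-numbered genes are argued against by the peak bases outside the repeat mask, at 4.97 times the rotation mean (permutation p = 0.0002). Repeat-masked bases made up 30.0% of the peak bases in these genes, against 29.8% after rotation (permutation p = 0.948). Peaks that reach from a repeat into unmasked sequence beside it cannot be told apart by these values and stay open. Differences between the mice and the reference, and reads longer or shorter than the 31-base words, stay open. No biological explanation was tested, since the samples form 1 group.

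Of the tRNA-Phe primer binding sites, 5 lay within a peak but 119 within 1 kb of a peak, and multi-copy sequence that the authors' filtering of alignments left without usable reads is a candidate explanation. Within 100 bases of these sites a median of 5.29% of the 31-base words occurred at 1 place in the genome, against 94.2% in the replicated peaks, which is consistent with it, but the tRNA-Pro sites had a lower median of 1.47% and 9.77% of them lay within a peak. None of the 635 tRNA-Phe sites with 10% or less of such words lay within a peak, nor did any of the 99 tRNA-Pro, 28 tRNA-Lys1,2 or 30 tRNA-Lys3 sites with as few. Among sites with more, 5 of 455 for tRNA-Phe (1.1%) and 17 of 75 for tRNA-Pro (22.7%) lay within a peak, a contrast that was not tested, so multi-copy sequence as the whole cause stays open. How the alignments were filtered is not given in the sources used here, and no biological explanation was tested.

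Most peaks of each replicate list overlapped no peak of the other, and weak peaks near the authors' threshold are a candidate cause. Of the peaks with q of 0.0001 or less, 79.3% in replicate 1 and 85.6% in replicate 2 were shared, against 25.8% and 26.3% of those with q above 0.05, which is consistent with it. Weakness as the whole cause stays open. With the 10000 peaks of lowest p kept from each list, 34.6% of those of replicate 1 were shared. That cut also removes partners of lower rank in the other list, so it cannot decide. A difference in length alone is argued against, since 39.4% of the peaks of the shorter list were shared. Peaks found in both lists were also wider, 557 against 392 bases at the median for other replicated peaks, and width was not separated from strength. The control files that differed between the replicates and the numbers of pooled embryos stay open, and no biological explanation was tested.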

How the results depend on the processing

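Of 302 alternative values for 45 results, 253 kept their direction and their side of the threshold, or moved by less than the spread (for counts, by less than 1.5 times). Of 99 for the 33 named genes, 77 moved by less than the spread and 22 by more, all of the 22 at the stricter threshold. The spread was the SD of the 2 replicates, which the value of either replicate alone cannot exceed. Only the 33 values at the stricter threshold could therefore move. The alternatives with peaks in both replicate lists and with single-copy peaks were chosen only after the data were seen. The cause was not tested for any of the changes that follow, except that fewer or more peaks were used where the list changed. The coding exon, intron, intergenic, GC, tRNA-Pro, tRNA-Lys1,2, last exon, vomeronasal, protocadherin and imprinted results kept their direction and call under every alternative run for them. With 50% of the peak the mean sharing of peaks was 26.4%, with 50% of both peaks 19.8% and with the 10000 top peaks of each list 35.2%. The rho of fold enrichment was 0.323 by -log10 p and 0.363 with 50% of the pooled peak. The replicated share was 57% at the stricter threshold and 12.2% with 50% of the pooled peak in both replicates. At the stricter threshold the coverage was 2.51 kb per Mb over all chromosomes, 7.73 on chromosome 7 and 0.641 on the X chromosome, and the 5' UTR ratio was 1.63 (adjusted permutation p = 0.0512). With the pooled list the ratio was 1.11 for 3' UTRs (adjusted permutation p = 0.171), 1.01 for repeat-masked bases, 1.01 for tRNA-Phe sites, 1.09 for X-linked families, 1.24 for pluripotency, 1.05 for progenitor, 0.895 for vascular and 1.15 for other organ genes, and there were 34115 domains. With each replicate list alone the ratio ranged from 1.48 to 1.72 for 5' UTRs, 1.18 to 1.20 for 3' UTRs, 0.871 to 1.19 for X-linked families, 1.40 to 2.09 for germline, 0.764 to 1.62 for progenitor, 0.845 to 1.30 for neuronal and 0.970 to 1.1 for vascular genes, and there were 22470 to 25827 domains with 44.4 to 47.2% of bases in those of 5 or more peaks. The 5' UTR, 3' UTR and neuronal changes came without replicate 2, and those of the X-linked, germline (adjusted permutation p = 0.132), progenitor and vascular lists without replicate 1. With peaks in both replicate lists the ratio was 1.04 for promoters, 6.67 for tRNA-Lys3 sites (adjusted permutation p = 0.0972) and 0 for Hox genes. Within 2 kb of the outer start of the gene it was 1.33 for C2H2 (adjusted permutation p = 0.849), 1.49 for Zfp-numbered (adjusted p = 0.653), 0.960 for Hox, 1.31 for pluripotency, 0 for neuronal and 0 for vascular genes. Within 1 kb of a peak tRNA-Phe sites reached 5.12 (adjusted permutation p = 0.0002). With 500 bases or more Hox genes stood at 0. On autosomes only the ratio was 1.41 for X-linked families, by then 4 genes, and 0.915 for neuronal genes. Against length-matched gene sets it was 1.67 for olfactory (adjusted permutation p = 0.000429), 0.752 for Hox and 0.163 for X-linked genes (adjusted p = 0.0274). Such sets ignore clusters and chromosomes. Merging at 5 kb put 39.5% of peak bases in domains of 5 or more peaks, and at 20 kb 54.9%. Counted by summit, the UTR results were lost (adjusted permutation p = 0.683 for 5' UTRs and 0.133 for 3' UTRs). Over the other alternatives the adjusted p ranged from 0.000429 to 0.849 for C2H2, to 0.653 for Zfp-numbered, to 0.132 for germline and to 0.317 for olfactory genes, from 0.0122 to 0.0750 for 5' UTRs, 0.00315 to 0.171 for 3' UTRs, 0.0274 to 1 for X-linked families, and 0.0002 to 0.0972 for tRNA-Lys3 and to 1 for tRNA-Phe sites. The lists whose direction turned had not passed the test with the replicated list. Read depth is not given in the sources used here, so what it limits is unknown.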

Other observations

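The split of clusters by coverage, the scan of gene families by name, the look at the strongest peaks and at the Ugt1a domain, and the motif test were chosen only after the gene list results were seen. Receptor clusters fell into heavily and sparsely marked ones. Of the 33 olfactory clusters, 5 held 59.2 to 181 kb of replicated peak per Mb and had a peak in 88 of their 169 genes. The other 28 held 0 to 29.9 kb per Mb, with a median of 3.01, and had a peak in 17 of 923 genes. The heavily marked ones lay on chromosomes 2 (36373519 to 37332772), 7 (6438688 to 6571401), 9 (18751507 to 20336094), 11 (73350783 to 74366218) and 19 (11826803 to 13921866). Of the 16 vomeronasal clusters, 9 held 58.3 to 143 kb per Mb, with a peak in 91 of 134 genes, and 7 held 0 to 36.4, with a peak in 7 of 169 genes. Of those 9, the cluster with the most genes (chromosome 17, 17703747 to 21314912) had a peak in 30 of 36 genes, whereas the 35 genes on chromosome 13 (22084440 to 23253906) had none. The split at 50 kb per Mb was set on these values, so it carries no test. Some of these clusters overlap clusters of another family, so the families were not marked separately there.

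The Ugt1a genes, glucuronosyltransferases that like the Pcdha and Pcdhg genes are read from alternative first exons, lay in a domain on chromosome 1 (88203645 to 88266131) with 50.4 kb of replicated peak in 62.5 kb, and 47.1 and 46.8 kb in replicates 1 and 2. Dnajb3, Mroh2a and Hjurp overlapped the same domain, and its peak bases were not divided among the genes. Among 324 gene families sharing a name stem, 0 passed the rotation test after adjustment, and 13 had an unadjusted p under 0.05, 8 of them with more peaks than rotated. A threshold of 0.05 over 324 families can give that many by chance. Of the 8, Nlrp, Ceacam and Skint are described here, picked after their values were seen. Kbtbd, Pip, Scgb, Klra and Cfap were the rest. Nlrp genes, of innate immunity and oocytes, held a peak in 11 of 17 (2.42 times the rotation mean, permutation p = 0.0084, adjusted p = 1), Ceacam adhesion genes in 9 of 15 (3.91 times, p = 0.0226, adjusted p = 1) and Skint genes in 10 of 11 (2.57 times, p = 0.0336, adjusted p = 1). Of the 100 replicated peaks of highest fold enrichment (6.08 or more), 21% had their summit in a coding exon and 12% in a promoter, against 1.68% and 4.25% of all replicated peaks. They were also wider, 1886.5 against 488 bases at the median.

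A hypothesis on the peaks of imprinted genes was that they carry the motif TGCCGC, which the zinc finger protein ZFP57 binds when methylated. The 90 such peaks that could be matched on width and GC content held 105 copies in 24 peaks, 1.1 per kb against 0.267 ± 0.0606 (SD) in the matched peaks, 4.10 times as many (permutation p = 0.0002, the smallest possible), which is consistent with the hypothesis. CG-rich sequence of any kind stays open: 35 other words of the same bases with 1 CG had a median ratio of 1.41, but the highest of them reached 4.93, above the motif. The motif therefore ranked 2 by ratio, and its excess cannot be told apart from that of CG-rich words by these values. Some other words lay in more of the peaks than the motif, such as CTCGGC in 28 and CCTCGG in 27, and most lay in fewer. The matched draws treat peaks as independent, although several peaks can lie in 1 gene and the copies were clumped, so the p is approximate. ZFP57 binding was not measured in these samples.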
